A study of Medicago sativa with 86 samples.

How the data were processed

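Messenger RNA of alfalfa (*Medicago sativa*) leaves was sequenced in 86 libraries. Per the labels, plants of the cultivars Agate and Saranac, each present as a class with effective and a class with ineffective nitrogen fixation, were inoculated with rhizobium, fed once a week with 6, 10 or 16 mM KNO3 in nutrient solution and kept in growth chambers at 420 or 600 ppm CO2. The labels do not say whether the ineffective class differs in the plant, in the bacterium or in both, nor whether a library holds 1 plant or several, so p-values measure the spread between these libraries. The CO2 levels were kept in separate chambers, per the labels' protocols, so CO2 level and chamber cannot be told apart in any comparison of CO2.

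The deposited table holds raw read counts per gene for 49095 gene identifiers, which the authors produced with featureCounts, per the submitters' processing notes. Its version, the aligner, the genome build, the annotation and the strand setting are not given in the sources used here. The libraries were made with a stranded mRNA kit from polyadenylated RNA, per the labels' protocols. Of the identifiers, 10349 had a count of 0 in every library. Reads that genes share with near-identical copies could have been split or dropped by the counting, and alfalfa plants of 1 cultivar can carry different alleles, so the level of a single gene in a single library is less certain than its count alone implies. None of the identifiers matched the reference table of gene names, which belongs to the assembly Bolivia_mono (0 of 49095 matched), so genes are given by the identifiers of the table, without names. For the same reason 30 lists of genes by function that had been fixed before the data were examined were not run, and neither were the genes that were to be named by function whatever their values.

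Each library was put in a group by its labels. This gave 85 libraries in 24 groups of cultivar, fixation class, nitrate and CO2 level, 11 of them with 3 libraries and 13 with 4. For 1 library the labels contradict each other on the fixation class, so it entered no comparison. Another library, replicate 3 of ineffective Saranac at 6 mM and 420 ppm, carries a number that lies among those of the 16 mM libraries. It was kept as labelled, and an alternative left it out. No 2 columns were identical. The total count was 13543807 to 25910031 per library with a median of 19895909.

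The main test was the quasi-likelihood F-test of edgeR 4.0.16 (R 4.3.3) on the counts as deposited, in 1 model with a coefficient for each of the 24 groups, TMM scaling and robust estimation of the dispersion. Genes were kept by filterByExpr with the groups, which left 24386. Contrasts weighted the groups of each side equally on the log scale, so where some groups are near 0 a log2 fold change can exceed the log ratio of the mean levels. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes with an adjusted p under 0.05 are called changed. The standard error of a log2 fold change was taken as its size over the square root of F. Levels are CPM, counts scaled to a common library total, with TMM scaling, as mean ± SD over the libraries of a side, which includes differences between the groups of that side.

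Before the data were examined, 16 contrasts were fixed. After a first look at the data 12 further contrasts were added: fixation at each CO2 level and in each cultivar, cultivar in each fixation class, nitrate at each CO2 level, the interactions of cultivar with fixation and with CO2, and the CO2 response at 6 mM against that at 10 mM and at 16 mM. All 28 are reported, whatever their outcome. The rule for single genes was also fixed beforehand. For the first 9 contrasts it takes genes with an adjusted p under 0.05, a mean of at least 1 CPM over the grouped libraries and a log2 fold change of the same sign in both cultivars, ranks them by log2 fold change and, where identifiers have no names, gives at most 2 that rose and 2 that fell. For the remaining contrasts only numbers of genes are given. The group of the 100 genes with the highest mean CPM was formed after the first look, from all grouped libraries and without regard to any contrast.

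Correlations between fold changes were computed across the 24386 genes on log2 CPM with a prior count of 2, between contrasts that share no library. Genes are not independent replicates, so the error given is a jackknife SE that leaves out each library in turn. A CO2 score places each library along the CO2 difference at 6 mM: -1 and 1 are the 420 and 600 ppm means at 6 mM, and a 6 mM library was left out of the means that it was scored against.

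The alternatives fixed beforehand were the replicate number as a block, the size factors of DESeq2 in the edgeR fit, the Wald test of DESeq2 1.42.0, no filter on low counts, each replicate number left out in turn, a model of the libraries of the contrast alone, and the library with the number out of order left out. Leaving out each single library in turn was planned with edgeR. It was done with limma-trend (limma 3.58.1) on log2 CPM, which is faster, and limma-trend was also run with all libraries. A further alternative left out the 2 libraries with the largest residual variance, replicate 1 of ineffective Agate at 420 ppm at 10 mM and at 16 mM. To see how many genes chance gives, the labels of 1 factor were shuffled 99 times within the cells of the other factors and tested with limma-trend, which with the real labels makes 100 splits.

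The procedure was tested on simulated counts with the overall mean and the dispersion of each gene and the library sizes of the real data. For each of 4 contrasts 200 genes were changed, 50 for each fold size. The real differences between groups were left out, and genes were drawn independently of each other. With 23824 genes tested, edgeR recovered 52% of the genes with a 2-fold change and 74% of those with a 4-fold change for CO2 in effective plants. For fixation at 6 mM it recovered 44% and 68%, for nitrate in ineffective plants 48% and 66%, and for the CO2 by fixation interaction 40% and 58%. Of 1.5-fold changes it recovered 28%, 28%, 20% and 24% for these contrasts in the same order. Among the 23586 unchanged genes it called 14, 8, 13 and 11. The simulation holds no variation that the genes of a library share, so these numbers do not give the error rate for the real data.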

Results

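Leaf transcriptomes of alfalfa were measured by RNA sequencing in plants of 2 cultivars, Agate and Saranac, with effective or ineffective nitrogen fixation, at 6, 10 or 16 mM KNO3 and 420 or 600 ppm CO2. The title of the series asks how nitrogen fixation bears on carbon and nitrogen balance and photosynthesis at elevated CO2, and the design allows the leaf response to CO2 to be compared between plants that fix nitrogen and plants that do not. The 24 groups held 3 or 4 libraries each, 85 in all. The total count per library was 20434798 ± 2554647 (SD, n = 42) at 420 ppm and 19521031 ± 2304024 (SD, n = 43) at 600 ppm. Genes are given by the identifiers of the count table, which the sources used here do not pair with names.

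CO2 level and line accounted for the main axes of variation. The first principal component held 14.2% of the variance, and CO2 level accounted for 58.2% of it. The second held 6.0%, of which cultivar accounted for 54.1% and fixation class for 13.1%. On that second axis the 21 libraries of ineffective Saranac lay between -87.3 and -42.2, apart from all others, the lowest of which was at -30.5. On the first axis 37 of 42 libraries at 420 ppm and 4 of 43 at 600 ppm lay above 0. The share of either component that nitrate level accounted for was 0.382% and 0.300%.

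**Figure D1:**
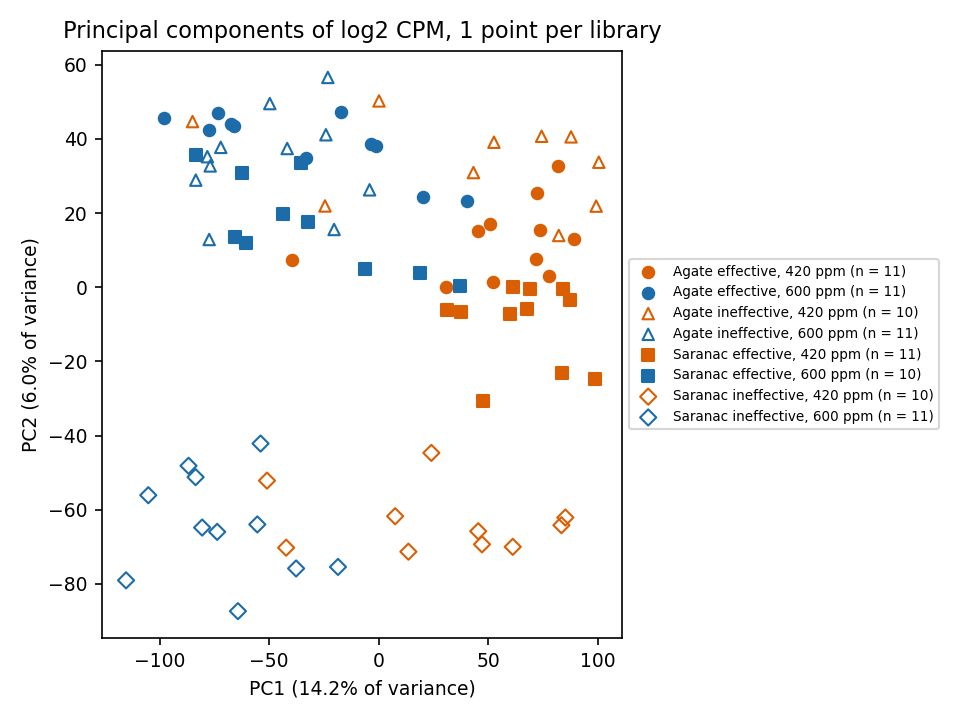
First and second principal components of log2 CPM over 24386 genes, 1 point per library, with colour for CO2 level and shape for cultivar and fixation class (filled, effective; open, ineffective). Libraries at 420 and 600 ppm lie mostly on opposite sides of the first axis (14.2% of variance), and ineffective Saranac lies apart on the second (6.0%).

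In effective plants 3907 genes rose and 3504 fell at 600 against 420 ppm CO2, 30.4% of those tested. The rise was led by a pair of identifiers. MsG0580024696.01 went from 0.762 ± 3.14 CPM (SD, n = 22) to 18.5 ± 18.7 CPM (SD, n = 21), a log2 fold change of 7.04 ± 1.02 (SE, adjusted p = 1.9e-07). MsG0580024719.01 went from 0.0710 ± 0.176 to 6.91 ± 9.98 CPM, a log2 fold change of 6.86 ± 1.04 (SE, adjusted p = 6.3e-07). Among the genes that fell, MsG0280007215.01 went from 1.70 ± 1.91 to 0.127 ± 0.316 CPM, a log2 fold change of -5.30 ± 1.00 (SE, adjusted p = 3.9e-05). MsG0280010631.01 went from 188 ± 359 to 26.8 ± 78.4 CPM, a log2 fold change of -4.77 ± 1.08 (SE, adjusted p = 0.00039), and without the libraries of replicate 4 its adjusted p was 0.085. The most abundant transcripts mostly fell: of the 100 genes with the highest mean CPM, 74 fell, 2 rose and 24 were not called. These 100 genes held 41.1 ± 3.62% of the counts (SD, n = 22) at 420 ppm and 32.6 ± 3.76% (SD, n = 21) at 600 ppm. The called genes changed by a median of 0.81 on the log2 scale, and 3055 of them by more than 1.

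In ineffective plants 4090 genes rose and 4368 fell at 600 ppm, 34.7% of those tested. MsG0780038656.01 rose from 1.66 ± 6.07 CPM (SD, n = 20) to 5.38 ± 8.44 CPM (SD, n = 22), a log2 fold change of 6.47 ± 1.20 (SE, adjusted p = 2.7e-05), with no counts in 13 of the 20 libraries at 420 ppm. MsG0280008442.01 rose from 17.2 ± 23.04 to 128 ± 100.3 CPM, a log2 fold change of 6.34 ± 0.97 (SE, adjusted p = 4.2e-07). MsG0280006731.01 was all but lost: it had 650 counts over the libraries at 420 ppm, in 18 of 20, and 1 count over the 22 libraries at 600 ppm, a ratio of 839 with an exact 95% interval of 150.1 to 33196 that covers counting error only (adjusted p = 8.8e-10). MsG0180001269.01 fell from 25.9 ± 79.3 to 0.105 ± 0.266 CPM, a log2 fold change of -7.64 ± 1.17 (SE, adjusted p = 4.2e-07), and its adjusted p was 1 without the libraries of replicate 2. Of the 100 most abundant genes 78 fell and 7 rose. Their share of the counts was 38.002 ± 6.91% (SD, n = 20) at 420 ppm and 25.5 ± 3.27% (SD, n = 22) at 600 ppm.

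The genes that responded to CO2 overlapped between the fixation classes. Both classes shared 1880 genes that rose, against 655 for independent lists, and 2120 that fell, against 628, while 223 were called in opposite directions, against 1288. The 2 contrasts share no library, and across genes their log2 fold changes had a Pearson r of 0.63 ± 0.059 (jackknife SE). Over all genes tested 73.3% had the same sign of CO2 response in both cultivars in effective plants and 72.1% in ineffective plants. The CO2 responses of Agate and Saranac had an r of 0.82 ± 0.025 across genes. The interaction of CO2 with cultivar called 0 genes with edgeR and 0 with limma-trend. DESeq2 called 145, and 1526 genes had an unadjusted p under 0.05 in edgeR. In limma-trend 1 gene was called without replicate 4 of effective Agate at 10 mM and 600 ppm.

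The CO2 response nonetheless differed between fixation classes in 2475 genes, 1078 with a higher and 1397 with a lower log2 change in ineffective plants. Of these, 1170 were called in ineffective plants and not in effective ones, 754 the other way round, 259 in both with the same direction and 223 in both with opposite directions, while 69 were called in neither. MsG0280010631.01 had a log2 fold change of -4.77 ± 1.08 in effective and 3.56 ± 1.23 in ineffective plants (SE), and the difference of 8.33 ± 1.60 had an adjusted p of 0.00030. MsG0380013534.01 likewise fell in effective plants (-4.43 ± 0.79) and rose in ineffective ones (1.92 ± 0.77), a difference of 6.35 ± 1.10 (adjusted p = 6.9e-05). MsG0480019192.01 rose in effective plants (4.11 ± 1.08) and fell in ineffective ones (-5.26 ± 1.10), a difference of -9.37 ± 1.54 (adjusted p = 3.5e-05). MsG0280006552.01 did so too (4.15 ± 1.08 and -3.52 ± 1.07), with a difference of -7.68 ± 1.52 (adjusted p = 0.00038). The levels of these identifiers were uneven between libraries. In effective Saranac at 420 ppm MsG0280010631.01 reached 1468 CPM against a median of 0.184 CPM (n = 11). Its median at 600 ppm was 0.162 CPM (n = 10), and in effective Agate its medians were 11.5 and 1.38 CPM (n = 11 each). MsG0380013534.01 reached 139 CPM in effective Saranac at 420 ppm, against a median of 0.577 CPM. The other 2 identifiers were uneven in ineffective plants at 420 ppm. MsG0480019192.01 reached 435 CPM in Agate and 822 CPM in Saranac, against medians of 0.494 and 0.763 CPM (n = 10 each). MsG0280006552.01 reached 13492 and 3634 CPM, against medians of 0.652 and 0.673 CPM. At 600 ppm the medians in ineffective Agate and Saranac were 0.0457 and 0.355 CPM for MsG0480019192.01 (n = 11 each). For MsG0280006552.01 they were 0.360 and 6.96 CPM, so in ineffective Saranac its median rose with CO2, against the fitted fall. Without the 2 libraries of largest residual variance, both of ineffective Agate, the differences of these 2 identifiers were -7.48 (adjusted p = 1.00) and -5.30 (adjusted p = 0.216). Of the 100 most abundant genes 32 had a lower and 5 a higher log2 change with CO2 in ineffective than in effective plants. Most of the 100 fell with CO2, with a median log2 fold change of -0.85 in ineffective and -0.48 in effective plants. The interaction count was 1516 without the libraries of replicate 1, 895 without those of replicate 2 and 1178 without those of replicate 4.

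The CO2 response was then compared at each nitrate level. In effective plants 4868 genes were called at 6 mM, 1053 at 10 mM and 2557 at 16 mM. In ineffective plants the counts were 5606, 2941 and 2727. Tested directly over both fixation classes, the CO2 response at 6 mM differed from that at 10 mM in 2309 genes. Of these, 1579 had a higher and 730 a lower log2 change at 6 mM. From the response at 16 mM it differed in 890 genes, 684 higher and 206 lower. These contrasts test each gene for a different response and do not test which level has the larger one. The CO2 score, on which the 6 mM means are set to -1 and 1, had a median of -0.841 (n = 13) at 420 ppm and 0.954 (n = 15) at 600 ppm at 6 mM, of -0.453 (n = 14) and 0.510 (n = 15) at 10 mM, and of -0.472 (n = 15) and 0.488 (n = 13) at 16 mM. The covariance across genes of the CO2 responses of effective and ineffective plants was 0.862 ± 0.075 (jackknife SE) at 6 mM, 0.174 ± 0.058 at 10 mM and 0.248 ± 0.093 at 16 mM. Of the 100 most abundant genes 2 had a higher log2 change with CO2 at 6 than at 16 mM and none a lower one.

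Single libraries moved some of these counts by over 1.5 times when each was left out in limma-trend. For effective plants at 10 mM, 913 genes became 446 without replicate 1 of Agate and 597 without replicate 2 of Saranac, both at 420 ppm. For effective plants at 16 mM, 2373 became 1579 and 1352 without replicates 2 and 3 of Saranac at 600 ppm. For the difference of 6 from 16 mM, 555 became 1075, 196 and 293 without replicates 1, 3 and 4 of effective Agate at 16 mM and 600 ppm, 321 without replicate 1 of effective Saranac in the same treatment, 316 without replicate 4 of ineffective Saranac at 16 mM and 420 ppm, and 347 without replicate 4 of ineffective Agate at 6 mM and 420 ppm. With all libraries of replicate 4 left out, edgeR called 0 genes for that difference. For the difference of 6 from 10 mM it called 852 without replicate 1, 1101 without replicate 3 and 1354 without replicate 4.

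**Figure D2:**
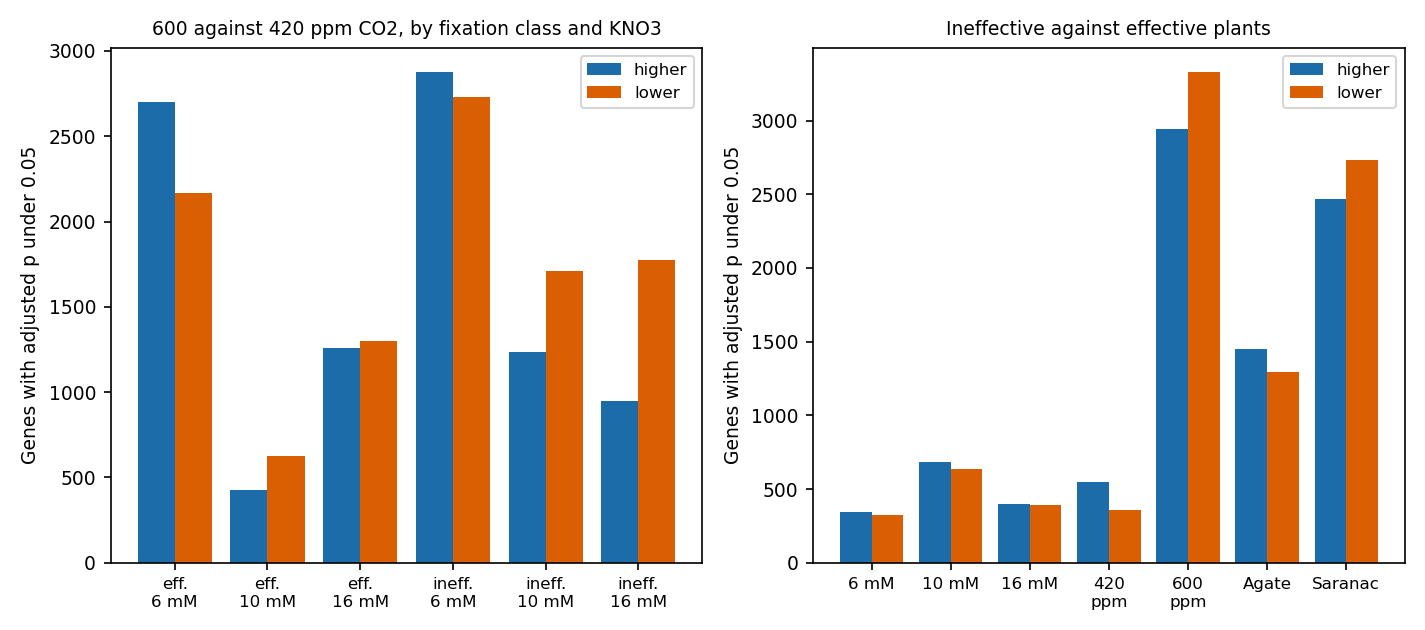
Numbers of genes with an adjusted p under 0.05 in edgeR that were higher (blue) or lower (orange). Left, 600 against 420 ppm CO2 in each fixation class and nitrate level, with the most genes at 6 mM; right, ineffective against effective plants within a nitrate level, a CO2 level or a cultivar, with 905 genes at 420 ppm and 6271 at 600 ppm.

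**Figure D3:**
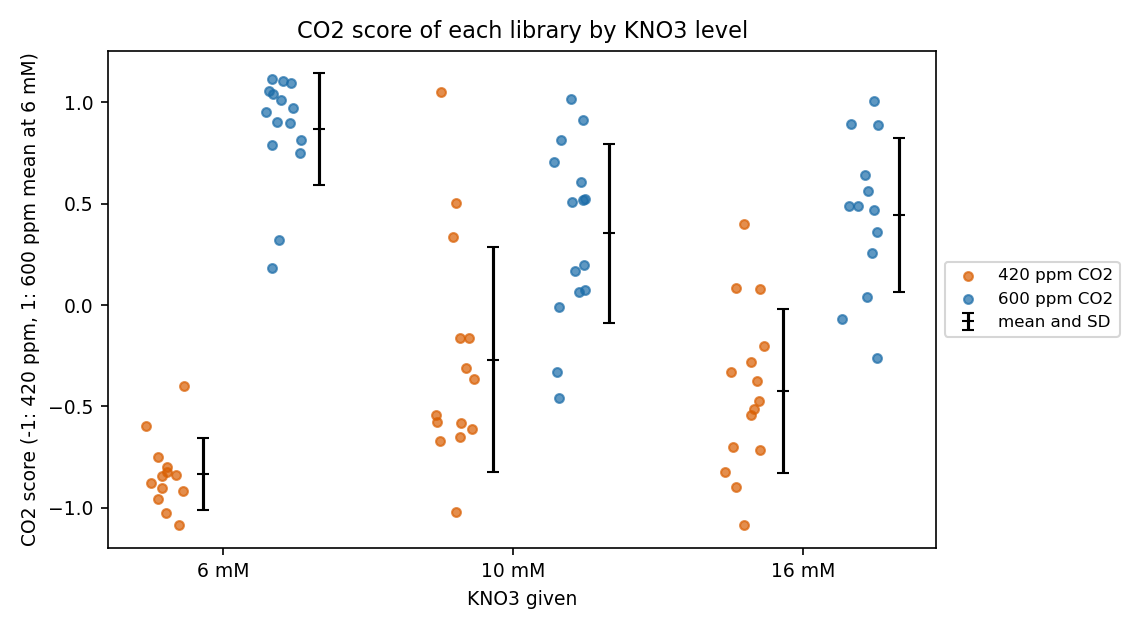
CO2 score of each library (points) by KNO3 level, with mean and SD (bars); -1 and 1 are the means of the 420 and 600 ppm libraries at 6 mM. The medians lie further apart at 6 mM (-0.841 and 0.954) than at 10 mM (-0.453 and 0.510) or 16 mM (-0.472 and 0.488).

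Ineffective plants were compared with effective plants at each nitrate level. At 6 mM 345 genes were higher and 327 lower in ineffective plants, at 10 mM 686 and 635, and at 16 mM 397 and 392. The same genes recurred: 80 were called at all 3 levels, 46 higher and 34 lower with none of mixed direction, against 1.18 for independent lists. MsG0780039352.01 was among the leading identifiers at 6 and at 16 mM. At 6 mM it stood at 58.97 ± 87.2 CPM in ineffective and 0.237 ± 0.510 CPM in effective plants (SD, n = 14 each), a log2 fold change of 6.47 ± 1.33 (SE, adjusted p = 0.0040), and at 16 mM at 54.2 ± 55.5 and 3.63 ± 11.1 CPM, a log2 fold change of 5.20 ± 1.16 (SE, adjusted p = 0.0097). MsG0880044857.01 was also higher at 6 mM (9.55 ± 7.93 against 0.126 ± 0.394 CPM, adjusted p = 0.0023), MsG0280010934.01 at 10 mM (adjusted p = 0.0015), and MsG0580030016.01 at 16 mM (adjusted p = 0.0031). MsG0180005083.01 was at the threshold at 10 mM (adjusted p = 0.04997), with a log2 fold change of 11.05 in Agate and 0.55 in Saranac, and lost its call under each alternative run on it but the size factors and the test of DESeq2. Of the genes lower in ineffective plants, MsG0880043723.01 had 0 counts in 14 ineffective libraries at 10 mM and 1000 counts in 5 of 15 effective ones, at least 325-fold lower against a floor of 3 counts over the group, a bound that covers counting error only (adjusted p = 0.015). Its adjusted p was 1 without replicate 2, 3 or 4, and over all nitrate levels ineffective Agate held 2.00 ± 3.86 CPM (SD, n = 10) at 420 ppm and 4.23 ± 8.79 CPM (SD, n = 11) at 600 ppm. MsG0480020491.01 had 2 counts over the ineffective libraries at 16 mM and 3353 in 7 of 14 effective ones, a ratio of 1748 with an exact 95% interval of 484 to 14440 that covers counting error only and not the spread between libraries (adjusted p = 0.0031). The other leading identifiers that were lower were MsG0480022947.01 (adjusted p = 0.0051) and MsG0680030543.01 (adjusted p = 0.047) at 6 mM, MsG0880045407.01 (adjusted p = 0.024) at 10 mM and MsG0580029554.01 (adjusted p = 0.035) at 16 mM. In the same order, 1 of 14, 8 of 14, 6 of 15 and 7 of 14 effective libraries had no counts of them. Of the 100 most abundant genes none were lower at 6 mM, 32 at 10 mM and 28 at 16 mM. The interaction of nitrate with fixation, which is the fixation difference at 6 minus that at 16 mM, called none of the 100, and 6 against 10 mM was not tested.

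Of the identifiers named for fixation, MsG0880044857.01 and MsG0280010934.01 kept their call under each edgeR and DESeq2 alternative run, and each of the others lost it when the libraries of at least 1 replicate number were left out. The counts also fell with fewer libraries. Without replicate 4, edgeR called 72 genes at 6 mM, 467 at 10 mM and 2 at 16 mM. At 10 mM the count was lowest without replicate 1, with 264 genes. In limma-trend 651 genes at 6 mM became 415 without replicate 3 of effective Saranac at 600 ppm, and 596 at 16 mM became 373 and 342 without replicate 1 of ineffective Agate at 600 and at 420 ppm, 392 without replicate 4 of effective Saranac at 420 ppm, and 903 and 249 without replicates 1 and 4 of ineffective Saranac at 420 ppm.

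More genes were called between fixation classes at elevated CO2, and the difference between classes depended on cultivar. Over all nitrate levels 546 genes were higher and 359 lower in ineffective plants at 420 ppm, and 2943 and 3328 at 600 ppm. The called genes differed by a median of 1.59 on the log2 scale at 420 ppm, 617 of 905 by more than 1. At 600 ppm the median was 0.70, with 2054 of 6271 by more than 1. These medians are over unlike sets of called genes and do not compare the size of effects over all genes. The interaction given above tests each gene for a different fixation effect at the CO2 levels, and does not test which level has the larger effects. At 600 ppm 61 of the 100 most abundant genes were lower in ineffective plants and 8 higher, against 1 and 0 at 420 ppm. In Agate 1448 genes were higher and 1295 lower in ineffective plants, in Saranac 2466 and 2734, and 2106 genes differed between the cultivars in this respect. Both cultivars shared 339 genes that were higher, against 146 for independent lists, and 292 that were lower, against 145, and 207 were called in opposite directions, against 293. Across genes the fixation difference of Agate at 420 ppm had an r of 0.38 ± 0.083 with that of Agate at 600 ppm, and in Saranac the same r was 0.40 ± 0.046, all from separate libraries. Between the cultivars r was 0.31 ± 0.041 at 600 ppm and 0.014 ± 0.12 at 420 ppm. The count at 420 ppm was 416 without the 2 libraries of largest residual variance and 91 without replicate 4, and in limma-trend 587 became 377 without replicate 4 of ineffective Saranac at 16 mM.

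**Figure D4:**
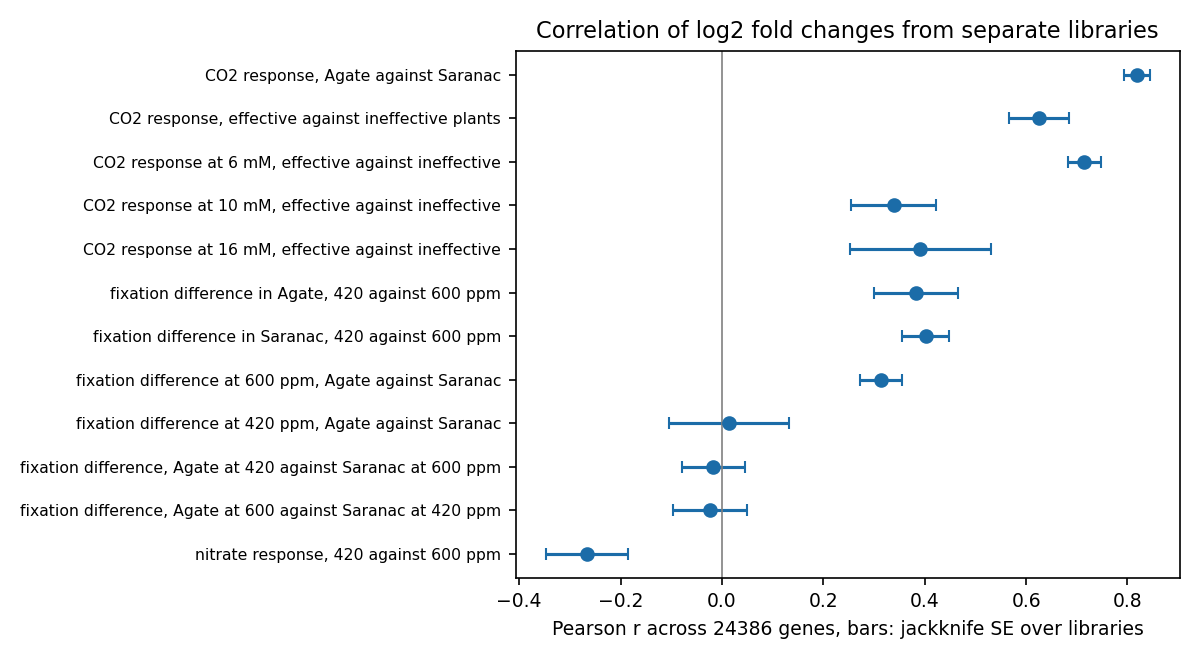
Pearson r across 24386 genes between log2 fold changes of contrasts that share no library, with the jackknife SE over libraries as bars. The CO2 responses of the cultivars have the highest r shown (0.82), and the fixation differences of different cultivars at different CO2 levels lie near 0.

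Nitrate supply changed few genes within a fixation class when averaged over CO2 levels. In effective plants 1 gene was lower at 6 than at 16 mM: MsG0380013843.01 at 29.9 ± 5.60 against 40.1 ± 5.42 CPM (SD, n = 14 each), a log2 fold change of -0.41 ± 0.078 (SE, adjusted p = 0.048). In ineffective plants 6 genes were higher and 13 lower at 6 mM. MsG0480022978.01 stood at 3.81 ± 4.68 against 0.352 ± 0.452 CPM, a log2 fold change of 3.10 ± 0.65 (adjusted p = 0.038), and MsG0380016800.01 at 3.17 ± 2.52 against 1.28 ± 0.523 CPM, one of 1.248 ± 0.26 (adjusted p = 0.038). MsG0280008438.01 was lower at 55.9 ± 58.8 against 121.6 ± 99.9 CPM, a log2 fold change of -6.29 ± 1.248 (adjusted p = 0.035) with no counts in 5 of the 14 libraries at 6 mM, and MsG0280008442.01, one of those that rose with CO2, had -6.05 ± 1.31 (adjusted p = 0.038). The mean levels of MsG0280008442.01 were close, at 69.6 ± 81.8 against 78.3 ± 78.4 CPM, and it had no counts in 6 of the 14 libraries at 6 mM and 1 of the 14 at 16 mM. The interaction of nitrate with fixation called 0 genes in edgeR, with 2102 at an unadjusted p under 0.05, 0 in limma-trend and 142 in DESeq2. Neither count for nitrate held up. Both were 0 with no filter on low counts, limma-trend called 2 and 0, and DESeq2 called 237 and 377. Leaving out single libraries in limma-trend gave 0 to 13 genes in effective and 0 to 7 in ineffective plants, the highest without replicate 2 of effective Agate and replicate 3 of ineffective Agate at 6 mM and 600 ppm. At an unadjusted p under 0.05 edgeR had 2020 genes in effective and 2894 in ineffective plants.

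At a single CO2 level, with both fixation classes together, more genes differed with nitrate than above, where each class was tested alone. Which of these choices gave the larger counts was not tested. At 420 ppm 92 genes were higher and 403 lower at 6 than at 16 mM, and at 600 ppm 60 were higher and 37 lower. The 2 lists shared 1 gene, against 0.611 for independent lists of that direction, and across genes the nitrate responses at the 2 CO2 levels had an r of -0.27 ± 0.081. The difference between them is the CO2 response at 6 against 16 mM given above. Both counts rested on few libraries. Without replicate 4 edgeR called 0 genes at 420 ppm and 6 at 600 ppm. In limma-trend 269 genes at 420 ppm became 463 without replicate 3 of ineffective Agate at 16 mM, 161 without replicate 4 of ineffective Saranac at 16 mM, and, at 6 mM, 172, 155 and 175 without replicate 4 of ineffective Agate, effective Saranac and ineffective Saranac. At 600 ppm the limma-trend count of 188 moved with many single libraries, between 32 without replicate 3 and 564 without replicate 1 of effective Agate at 16 mM.

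The cultivars differed in 3906 genes, 1799 higher and 2107 lower in Saranac. In effective plants 317 genes were higher and 290 lower in Saranac, and in ineffective plants 2467 and 3030. The called genes differed by a median of 1.71 on the log2 scale in effective and 0.98 in ineffective plants. Both medians are over unlike sets of called genes and do not compare the size of effects over all genes. The interaction of fixation with cultivar, with 2106 genes, tests each gene for a different cultivar effect in the fixation classes. It does not test which class has the larger effects. Of the 100 most abundant genes 94 were not called between cultivars.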

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

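Of the tests in this part, the comparisons of covariance were chosen after the results they bear on had been seen. The contrasts of fixation by cultivar, by CO2 level and of CO2 between nitrate levels were themselves added after a first look at the data.

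More genes were called for CO2 at 6 mM than at higher nitrate. The CO2 response differed between 6 and 10 mM in 2309 genes and between 6 and 16 mM in 890. These tests of each gene do not show which level has the larger response. For the 100 most abundant genes the median log2 fold change with CO2 was not largest in size at 6 mM. In effective plants it was -0.44 at 6 mM, -0.29 at 10 mM and -0.76 at 16 mM. In ineffective plants it was -0.86, -0.98 and -0.67 in the same order. Of the 10 and 16 mM libraries at 420 ppm, 4 of 29 scored above the lowest 6 mM library at 600 ppm, with 1.05 for replicate 1 of ineffective Agate at 10 mM, and of those at 600 ppm 1 of 28 scored below the highest 6 mM library at 420 ppm. The latter, replicate 3 of effective Agate at 10 mM, scored -0.456 and the library with that number at 420 ppm 0.501. Exchanged or wrong CO2 labels on single libraries thus stay open. The medians, which a few such libraries move little, lay further apart at 6 than at 10 mM by 0.832 (bootstrap SE 0.259). Against 16 mM the gap was 0.835 (SE 0.180). The score follows the CO2 difference at 6 mM, and the bootstrap kept that axis fixed. A response of equal size in partly different genes would thus score lower at 10 or 16 mM. The medians therefore do not decide whether the response was larger at 6 mM. Without the 2 libraries of largest residual variance 1596 genes differed between 6 and 10 mM, which argues against those libraries as the whole cause, while the size factors of DESeq2, with 2316 genes, hardly differ from TMM and decide nothing about scaling. For 6 against 16 mM edgeR called 187 genes without replicate 3 and 0 without replicate 4, while the covariance of the CO2 responses of the fixation classes was larger at 6 mM by 0.615 (jackknife SE 0.120); a candidate explanation is that low nitrate widens the leaf response to CO2, and differences between chambers or positions stay open, since chambers are not given per library.

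More genes were called between fixation classes at 600 than at 420 ppm, and 2475 genes differed in their CO2 response between fixation classes. The called genes differed by a larger median at 420 ppm (1.59 against 0.70 on the log2 scale). Those medians are over unlike sets of 905 and 6271 called genes, so they do not compare the size of effects over all genes. A wider spread between libraries at 420 ppm would lower the count there without lowering the covariance of the fixation differences of Agate and Saranac. That covariance was larger at 600 ppm by 0.166 (jackknife SE 0.0563), so the part of the difference that the cultivars share was larger there. It leaves out the part particular to each cultivar, so a wider spread at 420 ppm stays open as a cause of the lower count. Without the 2 libraries of largest residual variance 416 genes were called at 420 ppm, against 905 with them, so they did not hold the count down. Total counts were lower at 600 ppm, with a difference of -4.47%, so depth does not account for more genes there. A response to CO2 that depends on fixation may account for the pattern, and the chambers cannot be separated from CO2 level.

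The difference between fixation classes depended on cultivar in 2106 genes. Within Agate the covariance of the fixation differences at 420 and 600 ppm, from separate libraries, was 0.164, and within Saranac 0.204. These exceeded the mean covariance of pairs differing in both cultivar and CO2 level by 0.173 (jackknife SE 0.0309) and 0.214 (jackknife SE 0.0330). Spread between libraries alone would not give that excess. Across cultivars at the same CO2 level the covariance was 0.171 at 600 ppm, no smaller than within Agate, and 0.0055 at 420 ppm. Genes all but absent in 1 of the 4 lines made up 0.380% of the called genes, which argues against lost reads of whole genes as the main cause and leaves smaller shifts between near copies open. The labels do not say how the ineffective class was obtained in each cultivar, so differences in genetic background between the lines may account for the pattern as well as fixation.

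The CO2 responses of the 4 identifiers named for the interaction differed between the fixation classes by 8.33 for MsG0280010631.01, 6.35 for MsG0380013534.01, -9.37 for MsG0480019192.01 and -7.68 for MsG0280006552.01 on the log2 scale. The last 2 lost their call without replicate 1 (adjusted p = 1 and 0.211), without replicate 2 (0.0723 and 0.191) and without the 2 libraries of largest residual variance (1.00 and 0.216).

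Within groups of 4 libraries, 5 values stood apart from the other 3 by Dixon's criterion, where chance gives 3.25 in 65 tests. Replicate 1 of effective Agate at 10 mM and 600 ppm had 23938 genes detected, against 24781 to 24927. Replicate 4 of effective Saranac at 16 mM and 420 ppm had 23443, against 23942 to 24044. In replicate 3 of ineffective Agate at 6 mM and 600 ppm its own 100 most abundant genes held 36.9% of the counts, against 26.4 to 28.2%, and its first principal component was -23.2, against -78.2 to -72.1. Replicate 1 of effective Saranac at 10 mM and 420 ppm had a second principal component of -0.560, against -6.69 to -5.96. The library in no group had more than 3 counts for 21626 genes.

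Labels were shuffled within the other factors and tested with limma-trend, 100 splits for each contrast with the real one included. For 24 of the 28 contrasts 1 split, the real one, gave as many genes, and 1 in 100 is the smallest share that 100 splits can give. For those of a single factor that were fixed beforehand, each taken alone, chance can be excluded at that share. Fixation at each CO2 level and in each cultivar, nitrate at each CO2 level and cultivar in each fixation class were added after a first look. The splits do not repeat that choice, so for these contrasts they do not by themselves exclude chance. For CO2 by fixation, fixation by cultivar and CO2 at 6 against 10 or 16 mM, the shuffle also removes the average effect of the shuffled factor. There the splits test for any effect of that factor, so they do not exclude chance for the interaction itself. A small share does not bear on how far a count rests on a few libraries, as for nitrate at 420 ppm and CO2 at 6 against 16 mM. The real count and the highest of the other splits were 7155 and 3 for CO2 in effective plants, 8267 and 4 in ineffective plants, and 2085 and 4 for their interaction. They were 651 and 11, 1283 and 29, and 596 and 3 for fixation at 6, 10 and 16 mM, 587 and 8 at 420 ppm, 6185 and 15 at 600 ppm, 2657 and 161 in Agate, 5104 and 36 in Saranac, and 2249 and 2 for fixation by cultivar. For CO2 in effective plants at 6, 10 and 16 mM they were 4703 and 3836, 913 and 5, and 2373 and 8, and in ineffective plants 5513 and 4222, 2667 and 213, and 2316 and 9. At 6 mM a shuffle within cultivars can keep much of the real grouping. For the CO2 response at 6 against 10 and 16 mM they were 1947 and 4, and 555 and 28, for nitrate at 420 and 600 ppm 269 and 110, and 188 and 10, for cultivar 4216 and 2, and for cultivar in effective and ineffective plants 507 and 2, and 5609 and 12. Chance was not excluded for nitrate in effective plants, where 8 splits gave as many as the real 2 genes and the highest other gave 3. For nitrate in ineffective plants, nitrate by fixation and CO2 by cultivar the real limma-trend count was 0, which all 100 splits reach by construction, so the splits decide nothing there, nor about the 19 genes that edgeR called for nitrate in ineffective plants. The highest others gave 58, 37 and 32.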

How the results depend on the processing

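The alternatives that left out the 2 libraries of largest residual variance, used limma-trend, left out single libraries or concern an added contrast were chosen after seeing the data. The planned leave-out of single libraries was not run with edgeR and was done with limma-trend, the fit of the contrast's own libraries is not defined for 4 contrasts that use all groups, and the alternatives for lists of genes were not run, since no identifier matched a name. Counts are called the same within 1.5 times, and for the counts that moved the cause was not tested beyond the smaller number of libraries or genes that an alternative leaves by construction. The size factors of DESeq2 in the edgeR fit kept all 28 counts within that bound. The DESeq2 test moved these counts: 1441 for fixation at 6 mM, 2176 for fixation at 10 mM, 1718 for fixation at 16 mM, 237 for nitrate in effective plants, 377 for nitrate in ineffective plants, 142 for the nitrate by fixation interaction, 1912 for CO2 in effective plants at 10 mM, 1593 for fixation at 420 ppm, 145 for the CO2 by cultivar interaction, 1836 for CO2 at 6 against 16 mM, 1222 for nitrate at 420 ppm, 586 for nitrate at 600 ppm and 1166 for cultivar in effective plants. Without a filter the counts that moved were 410 for fixation at 6 mM, 424 for fixation at 16 mM, 0 for nitrate in effective plants, 0 for nitrate in ineffective plants, 565 for CO2 at 6 against 16 mM, 324 for nitrate at 420 ppm and 42 for nitrate at 600 ppm. A fit of the contrast's own libraries gave 371 for fixation at 6 mM, 261 for fixation at 16 mM, 0 for nitrate in effective plants, 2 for nitrate in ineffective plants, 675 for CO2 in effective plants at 10 mM, 1559 for CO2 in ineffective plants at 10 mM, 1269 for CO2 in ineffective plants at 16 mM, 499 for fixation at 420 ppm and 283 for nitrate at 420 ppm. Leaving out the library with the number out of order gave 2 for nitrate in effective plants, 0 for nitrate in ineffective plants and 59 for nitrate at 600 ppm. Leaving out the 2 libraries of largest residual variance gave 368 for fixation at 16 mM, 2 for nitrate in effective plants, 416 for fixation at 420 ppm, 2 for the CO2 by cultivar interaction and 207 for nitrate at 600 ppm. With limma-trend the counts that moved were 2 for nitrate in effective plants, 0 for nitrate in ineffective plants, 587 for fixation at 420 ppm, 555 for CO2 at 6 against 16 mM, 269 for nitrate at 420 ppm and 188 for nitrate at 600 ppm. 

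Without the libraries of a replicate number, in turn, edgeR called 5753 to 5805 genes for CO2 in effective plants, 5941 to 8084 for CO2 in ineffective plants, 895 to 2165 for the CO2 by fixation interaction, 72 to 250 for fixation at 6 mM, 264 to 1117 for fixation at 10 mM, 2 to 396 for fixation at 16 mM, 0 for nitrate in effective plants, 0 to 2 for nitrate in ineffective plants, 0 to 1 for the nitrate by fixation interaction, 2264 to 2499 for cultivar, 2407 to 4062 for CO2 in effective plants at 6 mM, 160 to 878 for CO2 in effective plants at 10 mM, 677 to 1730 for CO2 in effective plants at 16 mM, 2791 to 4897 for CO2 in ineffective plants at 6 mM, 927 to 3137 for CO2 in ineffective plants at 10 mM, 953 to 1810 for CO2 in ineffective plants at 16 mM, 91 to 1200 for fixation at 420 ppm, 4177 to 4673 for fixation at 600 ppm, 1420 to 1798 for fixation in Agate, 2710 to 3692 for fixation in Saranac, 883 to 1462 for the fixation by cultivar interaction, 0 for the CO2 by cultivar interaction, 0 to 719 for CO2 at 6 against 16 mM, 852 to 1704 for CO2 at 6 against 10 mM, 0 to 367 for nitrate at 420 ppm, 6 to 128 for nitrate at 600 ppm, 91 to 206 for cultivar in effective plants and 3482 to 4296 for cultivar in ineffective plants. Without a single library, in turn, limma-trend called 6616 to 7362 genes for CO2 in effective plants, 7722 to 8552 for CO2 in ineffective plants, 1865 to 2373 for the CO2 by fixation interaction, 415 to 895 for fixation at 6 mM, 866 to 1602 for fixation at 10 mM, 249 to 903 for fixation at 16 mM, 0 to 13 for nitrate in effective plants, 0 to 7 for nitrate in ineffective plants, 0 to 1 for the nitrate by fixation interaction, 3979 to 4364 for cultivar, 3758 to 4871 for CO2 in effective plants at 6 mM, 446 to 1017 for CO2 in effective plants at 10 mM, 1352 to 2669 for CO2 in effective plants at 16 mM, 4543 to 5847 for CO2 in ineffective plants at 6 mM, 1808 to 2959 for CO2 in ineffective plants at 10 mM, 1619 to 2473 for CO2 in ineffective plants at 16 mM, 377 to 681 for fixation at 420 ppm, 5698 to 6469 for fixation at 600 ppm, 2258 to 2834 for fixation in Agate, 4555 to 5297 for fixation in Saranac, 2062 to 2466 for the fixation by cultivar interaction, 0 to 1 for the CO2 by cultivar interaction, 196 to 1075 for CO2 at 6 against 16 mM, 1352 to 2348 for CO2 at 6 against 10 mM, 155 to 463 for nitrate at 420 ppm, 32 to 564 for nitrate at 600 ppm, 403 to 540 for cultivar in effective plants and 5210 to 5738 for cultivar in ineffective plants. No identifier named in the text reversed under the edgeR alternatives or, for the 27 of 29 values it gave, the DESeq2 test. Limma-trend was not used for single identifiers. Many calls were lost, however. Of the 29 values, 15, 16, 11 and 15 were no longer called without replicates 1, 2, 3 and 4. With no filter 8 were lost, and 9 of 25 in the fit of the contrast's own libraries. Leaving out the library numbered out of order lost 6, and leaving out the 2 libraries of largest residual variance 5. Of the 100 most abundant genes, 60 to 78 fell with CO2 in effective and 75 to 81 in ineffective plants over the alternatives run.

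With the replicate number as a block the counts were 0 for nitrate in effective plants and 0 for nitrate in ineffective plants. No other count moved by over 1.5 times with the block, and that of the CO2 by fixation interaction was 2373. Of the 29 values for named identifiers 8 were no longer called with the block: the 5 for nitrate, and MsG0680030543.01, MsG0180005083.01 and MsG0580029554.01 for fixation, with an adjusted p of 0.0930, 0.0536 and 0.107. The numbers do not pair the libraries: the mean correlation of residuals was -0.0025 for the same and 0.00088 for different numbers, 3 of 37 same-numbered pairs were over 0.1, and 21 of 85 libraries were closest to one with their own number. Depth limits genes of few counts, for which a fold change rests on a few libraries.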

Other observations

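The test of a hypothesis in this part was chosen after related results had been seen.

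The 100 most abundant leaf transcripts took a smaller share of the counts at 600 ppm. In effective plants the single libraries spanned 28.8 to 47.5% at 420 ppm and 26.3 to 40.9% at 600 ppm, and in ineffective plants 19.8 to 45.3% and 20.2 to 35.8%. Of these genes 62 fell with CO2 in effective plants at 16 mM, 13 at 10 mM and 25 at 6 mM, and in ineffective plants 58, 69 and 67. Over both fixation classes the CO2 response at 6 mM differed from that at 16 mM in 2 of the 100 and from that at 10 mM in 4, and the levels were not tested against each other within a class. Their median log2 fold change with CO2 was -0.48 in effective and -0.85 in ineffective plants, against 0.020 and 0.0015 over all genes tested. The group was formed after a first look at the data, and its genes have no names in the sources used here.

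The library that the labels put in no group was given 10 mM KNO3 and 420 ppm CO2. Its total count was 19724147, and 24882 genes had a count above 0.

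A hypothesis was that plants without effective fixation differ at 6 mM in the same genes as plants given less nitrate. It predicts that the fixation difference at 6 mM in a cultivar correlates across genes with the nitrate response of ineffective plants of the other cultivar. Pearson r was 0.037 ± 0.064 (jackknife SE) for Agate against ineffective Saranac and 0.027 ± 0.065 for Saranac against ineffective Agate, so the data gave no support for it. Genes are not independent replicates. The test sets a cultivar against the other, and their fixation differences had an r of 0.014 at 420 ppm and 0.31 at 600 ppm. For nitrate in ineffective plants edgeR called 19 genes. An r near 0 could thus arise even if the hypothesis held. The nitrate response in this test was averaged over CO2 levels. With all lines together the nitrate responses at 420 and 600 ppm had r = -0.27 ± 0.081 across genes, so the average may partly cancel and a relation at a single CO2 level was not tested.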
